A study of Homo sapiens with 12 samples.

How the data were processed

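RNA levels were measured in 12 Illumina sequencing libraries from BT549, an established human triple-negative breast cancer cell line, per the labels. Cells carried either a pool of non-targeting siRNAs (the control arm) or a mixture of siRNA pools against FOSL1 and JUN (the knockdown arm). In each arm, cells received the solvent DMSO or the PARP inhibitor olaparib for 48 h, per the labels. Each of the 4 groups held 3 libraries. The dose of olaparib, the aligner, the counting tool, the genome build and the strand setting were not given in the sources used here. The labels do not give the amount of siRNA in either arm. Reads were made from base calls with bcl2fastq 2.20.0.422, per the submitters' processing notes.

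The authors deposited a table of raw counts per gene, with an Entrez identifier, a symbol and a length for each of 27046 genes and 1 column per library, per the file headers. These counts were whole numbers with a different total in each library. The authors also deposited a table of log2 fold changes for the same 6 contrasts, and the p-value column used from it held their false discovery rates, per the file headers. That table listed likelihood-ratio statistics, and the tool behind it was not named. The rescaled forms of the same counts were not used here. Rows without a gene symbol numbered 51, held between 0.00223% and 0.00311% of a library's counts, and 4 of them passed the expression filter. They were never named. Genes with near-identical copies, such as ribosomal protein genes with their pseudogenes, histones and the FAM72 family, are uncertain because the counting rule for shared reads is not known, and likewise genes that overlap an antisense partner.

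Library totals ran from 13763179 to 39715900 counts. Genes were tested where at least 3 libraries had more than 1 CPM (a gene's count scaled to its library's total), which left 12122 genes. The untested genes held between 0.0697% and 0.0953% of a library's counts. Normalization factors came from the TMM method. A quasi-likelihood model with robust dispersion was fitted in edgeR 4.0.16 over all 12 libraries and 4 groups, with 8 residual degrees of freedom, and each contrast was tested with the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over the genes of 1 contrast, and a gene was called changed below 0.05. The standard error (SE) of a log2 fold change was derived from the F statistic. The common dispersion was 0.00372, a biological coefficient of variation of 6.1%. The 6 contrasts were olaparib against DMSO in each arm, knockdown against control in each solvent or drug condition, the difference between the arms in the olaparib effect (an interaction), and knockdown with olaparib against control with DMSO.

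A total of 38 gene lists with 918 entries was fixed before the data were examined, as were the groups, the tests, the rule for named genes and all alternatives except those stated to be later. The table held 905 of these entries and 755 were tested. The lists were AP-1 family, described AP-1 and FRA-1 targets, p53 pathway targets, homologous recombination, Fanconi anaemia and checkpoint, PARP family and base excision repair, non-homologous end joining and POLQ, DNA replication and S phase, G2/M and mitosis, replication-dependent histones, type I interferon response, cGAS-STING pathway, antigen presentation by MHC class I, NF-kB targets and cytokines, BCL2 family, caspases and death receptors, mesenchymal genes, epithelial genes, luminal breast markers, collagens, integrins, YAP/TEAD targets, TGF-beta targets, MAPK feedback genes, growth factor ligands and receptors, integrated stress and unfolded protein response, heat shock and chaperones, NRF2 targets, cholesterol and sterol biosynthesis, hypoxia and glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, lysosome and autophagy, senescence secretome, drug efflux transporters, mitochondrially encoded genes, haematopoietic cell markers and endothelial cell markers. Some genes stood in more than 1 list.

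Lists with at least 5 tested members, 35 in all, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2. Camera asks whether a list's members moved further in a direction than the other genes did. It ran with a preset correlation between genes of 0.01, and was repeated with the correlation estimated from the data. The fry test was an alternative. Its directional p-value asks whether a list's genes move, on balance, to one side, its mixed p-value whether they change in either direction, and neither compares the list with other genes. Counts of list members that passed were taken over all genes tested and also with p-values adjusted over the list alone.

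The genes named in each comparison were FOSL1 and JUN, then the 5 largest rises and 5 largest falls among genes below an adjusted p of 0.05 with a mean of at least 3 on the log2 CPM scale and, in comparisons of 2 groups, no overlap between the groups' libraries. From each of the 6 lists with the smallest camera p-values, the 3 members with the smallest p-values in the list's direction were added. Members of the AP-1 family could be named anywhere. Some genes that the rule takes are not reported here. Chance alone gives no overlap for 10% of genes with 3 libraries against 3. Levels are given as CPM with the SD over 3 libraries.

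Alternatives were DESeq2 size factors in the edgeR model, the DESeq2 1.42.0 Wald test, limma-voom, the default filter of edgeR, no expression filter, a model with the replicate number as a block, each library left out in turn, only the 2 groups compared, an adjusted p below 0.01, and a minimum log2 fold change of 1 in size. Chosen after seeing the data were offsets for each library's trend over GC content and gene length (lowess with a span of 0.3), counts thinned to the smallest library total, and a model without both libraries with the strongest GC trend. GC content was taken from the longest GENCODE v29 transcript of each symbol and was found for 11911 tested genes (98.3%). The effect of these alternatives is given in the closing section and beside the results they changed. Python 3.11.15 and matplotlib 3.10.9 drew the figures, and R 4.3.3 ran the tests.

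The gene test was tested on simulated counts with the real means and library totals, in which 50 genes at each of 4 fold sizes were changed among 12122. For olaparib in the control arm, 24% of genes changed by 1.25-fold, 76% at 1.5-fold, 92% at 2-fold and 100% at 4-fold were called, with 8 of 11922 unchanged genes called. For the interaction these shares were 12%, 66%, 84% and 96%, with 9 unchanged genes called. For knockdown in DMSO they were 50%, 86%, 92% and 100%, with 11 unchanged genes called. The simulated counts had the same spread of a gene in all 4 groups and no GC trend, so these values hold for that setting only. In a simulation of knockdown in DMSO with the 28 interferon genes raised by 1.5-fold, camera called that list and 0 of the other lists. The simulated genes were drawn independently of each other, so this run cannot show how often lists of correlated genes are called falsely. Replicate pairs within a group had Pearson correlations of log2 CPM between 0.991 and 0.996, and every pair differed by more than sampling noise. The chi-square per degree of freedom of a pair ran from 1.765 to 3.958 in the control groups and from 5.058 to 13.13 in the knockdown groups. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.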

Results

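The series measured RNA levels in BT549 cells, a triple-negative breast cancer line with mesenchymal features, after knockdown of 2 subunits of the AP-1 transcription factor and after treatment with olaparib, an inhibitor of PARP1 and PARP2. FOSL1 encodes FRA-1, a partner of JUN in AP-1 dimers. The design crossed the siRNA (non-targeting control, or FOSL1 and JUN together) with the treatment (DMSO or olaparib for 48 h), with 3 libraries in each of the 4 groups. Its stated purpose was to profile the cells under PARP inhibition, AP-1 knockdown or both. Totals were 14320335, 16815526 and 16823795 counts in control cells with DMSO, and 16538002, 15939776 and 23451054 in control cells with olaparib. In knockdown cells they were 13763179, 19638688 and 27625042 with DMSO, and 16047066, 39715900 and 14728327 with olaparib. No gene took more than 1.02% of a library. In a principal component analysis of the 12 libraries, the first component held 48.3% of the variance and the second 26.2%.

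Both targeted genes were lower in every knockdown library than in every control library under the same treatment. FOSL1 (Entrez 8061) stood at 74.8, 71.4 and 68.5 CPM in control cells with DMSO and at 29.02, 27.5 and 23.8 CPM in knockdown cells with DMSO. With olaparib it stood at 124, 136 and 117 CPM in control cells and at 21.7, 22.3 and 19.2 CPM in knockdown cells. JUN (Entrez 3725) stood at 161, 174 and 155 CPM in control cells with DMSO, at 157, 172 and 161 CPM in control cells with olaparib, at 56.2, 62.3 and 68.7 CPM in knockdown cells with DMSO, and at 49.7, 40.7 and 35.8 CPM in knockdown cells with olaparib. The remaining share of the control level in DMSO was 37.4% for FOSL1 and 38.2% for JUN. In olaparib it was 16.8% and 25.8%.

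**Figure D1:**
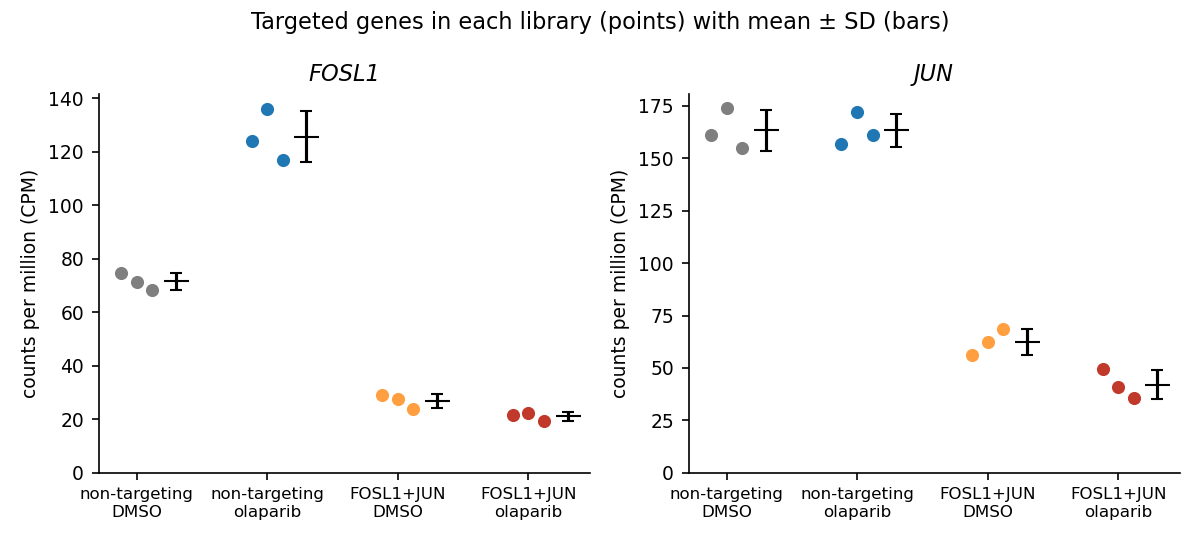
Level of FOSL1 and of JUN in CPM on the vertical axis for the 4 groups, with 1 point per library and bars at the mean ± SD of 3 libraries. FOSL1 rose with olaparib in control cells, from 71.6 to 126 CPM, and stayed at or below 29.02 CPM in all 6 knockdown libraries.

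Olaparib was compared with DMSO in control cells to show how the drug alone altered RNA levels. The largest rise under the naming rule was that of CTGF, a secreted matricellular protein and described target of YAP and TGF-beta, which went from 137 ± 2.61 to 1130 ± 59 CPM (SD, n = 3), a log2 fold change of 3.04 (SE 0.0652) and an 8.23-fold rise. TXNIP, a thioredoxin-binding protein that restrains glucose uptake, rose 5.73-fold (log2 2.52, SE 0.0863). GDF15, a stress-induced cytokine, rose 4.81-fold (log2 2.27, SE 0.23), and CRISPLD2 and CITED4 rose 4.47-fold and 4.44-fold. PFKFB4, a regulator of glycolysis, fell from 40.9 ± 3.99 to 11.1 ± 1.58 CPM (log2 -1.88, SE 0.0998). DEPP1, TCF7, RAB7B and FAM46A followed, with log2 fold changes of -1.70, -1.54, -1.49 and -1.39. In all, 5676 of 12122 genes changed (46.8%), 2866 up and 2810 down, with a median fold of 1.29 among them, and 372 changed at least 2-fold.

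The MAPK feedback and AP-1 family lists were higher with olaparib in control cells. MAPK feedback genes are induced by ERK signalling, and some of them restrain it. Of 22 tested, 15 rose and 2 fell (16 and 2 adjusted over the list alone), with a list median of 0.80 on the log2 scale. DUSP4, a MAP kinase phosphatase, rose 3.12-fold (log2 1.64, SE 0.0545), the transcription factor MYC rose 2.93-fold (log2 1.55, SE 0.05), and SPRY4 rose 2.26-fold. The camera adjusted p of this list was 9.08e-08, or 0.0325 with an estimated correlation. Of 16 AP-1 family genes, 10 rose and none fell (11 and 0 adjusted over the list alone). FOSL1 rose by 0.81 (SE 0.074, edgeR adjusted p = 5.79e-08), FOSL2 by 0.99, FOS by 1.20, FOSB by 0.95 and ATF7 by 0.70 on the log2 scale, while JUN had a log2 fold change of -0.00308 (edgeR adjusted p = 0.981). The AP-1 family list had a camera adjusted p of 0.000131, or 0.0429 with an estimated correlation. Among described AP-1 and FRA-1 targets 17 of 26 rose and 2 fell (18 and 2 adjusted over the list alone), including ZEB1 (log2 1.30), DUSP1 (log2 1.37) and LIF (log2 1.42), with a camera adjusted p of 0.00011. That call was not kept with an estimated correlation (adjusted p = 0.0585 with an estimated correlation).

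G2/M, ribosomal protein and TGF-beta target lists were higher with olaparib in control cells, and the hypoxia and glycolysis list was lower. Of 40 G2/M and mitosis genes, 31 rose and 1 fell (32 and 1 adjusted over the list alone), with NEK2 at a log2 fold change of 0.86, and CDC25B and KIF2C each at 0.67. This list had a camera adjusted p of 1.58e-08, and an adjusted p = 0.181 with an estimated correlation. Of 43 ribosomal protein genes, 40 rose and none fell (41 and 0 adjusted over the list alone) by small amounts, such as RPL12 at 0.44 and RPL10A at 0.35 (camera adjusted p = 1.05e-10, adjusted p = 0.196 with an estimated correlation). Reads of these genes may be shared with pseudogenes. Of 19 TGF-beta targets 14 rose and 2 fell (14 and 2 adjusted over the list alone), among them INHBA, a subunit of activin, at 1.75 and TGFB1I1 at 1.16 (camera adjusted p = 9.45e-05, adjusted p = 0.11 with an estimated correlation). Hypoxia and glycolysis genes went the other way, with 20 of 29 down and 4 up (20 and 5 adjusted over the list alone, camera adjusted p = 0.000434, adjusted p = 0.181 with an estimated correlation).

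Further lists passed camera in control cells with olaparib, each lost with an estimated correlation. Among NF-kB targets and cytokines 12 of 17 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.00058, adjusted p = 0.126 with an estimated correlation). For growth factor ligands and receptors the counts were 13 up and 0 down of 21 (13 and 1 adjusted over the list alone), with a camera adjusted p of 0.00108 and an adjusted p = 0.115 with an estimated correlation. For the integrated stress and unfolded protein response they were 16 and 3 of 25 (17 and 3 adjusted over the list alone), with 0.00128 and an adjusted p = 0.11 with an estimated correlation. Mesenchymal genes gave 13 up and 4 down of 23 (14 and 5 adjusted over the list alone), with a camera adjusted p of 0.00188 and an adjusted p = 0.181 with an estimated correlation. YAP/TEAD targets gave 11 and 3 of 21 (11 and 3 adjusted over the list alone), with 0.00262 and an adjusted p = 0.178 with an estimated correlation. Lysosome and autophagy genes gave 12 and 1 of 27 (12 and 1 adjusted over the list alone), with 0.00917 and an adjusted p = 0.281 with an estimated correlation. The senescence secretome gave 15 and 3 of 23 (15 and 4 adjusted over the list alone), with 0.0135 and an adjusted p = 0.181 with an estimated correlation. Replication-dependent histones, whose copies share sequence, gave 4 up and 0 down of 9 (5 and 0 adjusted over the list alone), with 0.0255 and an adjusted p = 0.126 with an estimated correlation, and 0.125 with GC content and length offsets, where the median went from 0.365 to 0.329. The cGAS-STING pathway was lower, with 6 of 11 down and 1 up (6 and 1 adjusted over the list alone), a camera adjusted p of 0.0255 and an adjusted p = 0.126 with an estimated correlation.

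DNA repair lists did not pass camera in control cells with olaparib. Homologous recombination gave 6 up and 6 down of 30 (6 and 6 adjusted over the list alone, camera adjusted p = 0.552), Fanconi anaemia and checkpoint 9 and 6 of 28 (12 and 7 adjusted over the list alone, 0.513), PARP family and base excision repair 6 and 9 of 26 (6 and 9 adjusted over the list alone, 0.419), and non-homologous end joining and POLQ 1 and 4 of 11 (1 and 4 adjusted over the list alone, 0.843). DNA replication and S phase gave 12 and 15 of 40 (12 and 15 adjusted over the list alone, 0.582). Of 26 p53 pathway targets 8 rose and 4 fell (8 and 4 adjusted over the list alone, 0.128). The type I interferon list gave 3 up and 3 down of 28 (3 and 3 adjusted over the list alone, 0.913). The camera adjusted p was 0.611 for the BCL2 family (4 up and 0 down of 13), 0.855 for caspases and death receptors (4 and 6 of 19), 0.15 for epithelial genes (4 and 2 of 9), 0.578 for collagens (6 and 4 of 17) and 0.918 for integrins (2 and 2 of 12). It was 0.929 for luminal breast markers (2 and 3 of 9), 0.331 for heat shock and chaperones (4 and 8 of 14), 0.293 for NRF2 targets (8 and 5 of 18), 0.578 for cholesterol and sterol biosynthesis (2 and 5 of 28), 0.929 for oxidative phosphorylation (6 and 1 of 32) and 0.449 for drug efflux transporters (2 and 4 of 10). Antigen presentation gave 1 up and 3 down of 8 (0.882), and its median of 0.04 and mean of 0.14 stood above 0 while the test pointed down. Collagens and integrins had a median below 0, a mean above 0 and a test pointing up, caspases a median above 0 with a mean and test below, and oxidative phosphorylation a median and mean below 0 with a test pointing up.

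The same drug effect was then measured in cells with FOSL1 and JUN knockdown. GDF15 rose 5.47-fold (log2 2.45, SE 0.226, n = 3) and ACTA2, smooth muscle actin, rose 5.16-fold from 158 to 813 CPM (log2 2.37, SE 0.0681). CRISPLD2 rose 4.03-fold, CTGF 3.94-fold and IGFBP4 3.34-fold. DEPP1, TCF7 and PFKFB4 fell again, by 2.24, 1.78 and 1.64 on the log2 scale, and AHDC1 and NOL3 had log2 fold changes of -1.34 and -1.32. FOSL1 and JUN, low at the outset, fell further by 0.32 (SE 0.0847, edgeR adjusted p = 0.00396) and 0.58 (SE 0.101, edgeR adjusted p = 0.000333). In all 5823 genes changed (48.0%), 2918 up and 2905 down, with 293 at least 2-fold. This count rests on a spread shared by all 4 groups. With only the 2 groups compared, 2490 genes rose and 2399 fell, against 3382 and 3261 for olaparib in control cells.

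Most members of the G2/M and homologous recombination lists rose with olaparib in knockdown cells. Of 40 G2/M genes 37 rose and none fell (37 and 0 adjusted over the list alone), with TOP2A, a mitotic topoisomerase, up 2.13-fold (log2 1.09, SE 0.0632), NEK2 up 2.06-fold and KIF2C up 1.82-fold (camera adjusted p = 3.72e-17, adjusted p = 0.134 with an estimated correlation). Of 30 homologous recombination genes 21 rose and 2 fell (22 and 2 adjusted over the list alone), among them RAD54B at a log2 fold change of 0.81, the helicase BLM at 0.70 and RBBP8, which starts end resection, at 0.69. The camera adjusted p was 0.000148, and the adjusted p = 0.125 with an estimated correlation. Of 28 Fanconi anaemia and checkpoint genes 15 rose and 4 fell (15 and 4 adjusted over the list alone, camera adjusted p = 0.0206, adjusted p = 0.174 with an estimated correlation). Stress response genes rose in 19 of 25 cases and fell in 2 (20 and 2 adjusted over the list alone), including DDIT3 (log2 0.96), PPP1R15A (log2 0.91) and ASNS (log2 0.69), with a camera adjusted p of 2.44e-06 and an adjusted p = 0.0713 with an estimated correlation. Ribosomal protein genes gave 40 up and 0 down of 43 (40 and 0 adjusted over the list alone), such as RPL12 (log2 0.44), RPL9 (log2 0.39) and RPL4 (log2 0.37), with 2.52e-09 and an adjusted p = 0.266 with an estimated correlation. MAPK feedback genes gave 14 and 3 of 22 (14 and 3 adjusted over the list alone), with DUSP4 at 1.28, MYC at 1.16 and SPRY2 at 0.74 on the log2 scale, a camera adjusted p of 0.000148 and an adjusted p = 0.1 with an estimated correlation. Hypoxia and glycolysis genes fell in 25 of 29 cases and rose in 3 (25 and 3 adjusted over the list alone), with BNIP3 at -0.97 and ALDOC at -0.94 (camera adjusted p = 1.46e-07, adjusted p = 0.125 with an estimated correlation).

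A further 3 lists passed in knockdown cells with olaparib, and each was lost without library 1 of the knockdown olaparib group. They were YAP/TEAD targets (10 up and 2 down of 21, 11 and 2 adjusted over the list alone, camera adjusted p = 0.0206, 0.0561 without that library), TGF-beta targets (8 and 2 of 19, 8 and 2 adjusted over the list alone, 0.0206, then 0.0738) and the senescence secretome (14 and 3 of 23, 14 and 3 adjusted over the list alone, 0.0292, then 0.0825). Each had an adjusted p = 0.263 with an estimated correlation. AP-1 family genes gave 7 up and 2 down of 16 (7 and 2 adjusted over the list alone) and did not pass (camera adjusted p = 0.0681, 0.0263 with GC content and length offsets, 0.12 with offsets and an estimated correlation), with FOSL2 up by 0.82 and FOS up by 0.71 on the log2 scale. Its 2 falling members were the siRNA targets, and without them 7 of 14 rose and 0 fell, with a median of 0.32 and an unadjusted camera p of 0.00277 (0.013 with an estimated correlation). Described AP-1 and FRA-1 targets gave 13 and 6 of 26 (15 and 6 adjusted over the list alone, camera adjusted p = 0.064, 0.0234 with the offsets, 0.12 with offsets and an estimated correlation). Type I interferon genes gave 6 and 5 of 28 (6 and 5 adjusted over the list alone, 0.934), with a median of -0.06 and a mean of 0.03.

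Knockdown was compared with control in DMSO to show what the siRNA mixture against FOSL1 and JUN altered without the drug. Interferon-induced genes made up the 3 largest rises under the naming rule. IFIT2, an antiviral RNA-binding protein, rose 7.79-fold from 3.67 ± 0.819 to 29.01 ± 1.00 CPM (log2 2.96, SE 0.11, n = 3), IFIT3 rose 6.61-fold and IFIT1 rose 5.72-fold. OASL, another antiviral protein, rose 19.7-fold from 0.882 to 17.7 CPM (log2 4.30, SE 0.133). TGM2, a transglutaminase, and CLCA2 rose 5.71-fold and 5.04-fold. FOSL1 and JUN fell by 1.43 (SE 0.0799) and 1.38 (SE 0.0967) on the log2 scale. COL13A1, a transmembrane collagen, had a log2 fold change of -2.05, the ligand EFNB2 of -1.95, GNG4 of -1.84, NPTX1 of -1.80 and ACTA2 of -1.69. In all 3624 genes changed (29.9%), 1780 up and 1844 down, with 288 at least 2-fold.

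Of 28 tested type I interferon genes 21 rose and none fell with knockdown in DMSO (22 and 0 adjusted over the list alone), with a list median of 1.41 on the log2 scale and a camera adjusted p of 9.76e-17, or 0.00224 with an estimated correlation. Of 11 cGAS-STING genes 5 rose and none fell (5 and 0 adjusted over the list alone), led by TMEM173, which encodes the adaptor STING, at 4.97-fold (log2 2.31, SE 0.12), the cyclic dinucleotide hydrolase ENPP1 at 1.94-fold and IRF3 (log2 0.33, SE 0.0605). This list had a camera adjusted p of 0.00871 and an adjusted p = 0.121 with an estimated correlation. Among NF-kB targets and cytokines 11 of 17 rose and 1 fell (12 and 1 adjusted over the list alone), with CCL2 up 2.97-fold, CSF1 up 2.39-fold and ICAM1 up 1.34-fold (camera adjusted p = 0.000294, adjusted p = 0.189 with an estimated correlation). Antigen presentation gave 4 up and 0 down of 8 (6 and 0 adjusted over the list alone, camera adjusted p = 0.0154, adjusted p = 0.212 with an estimated correlation, 0.0528 with thinned counts, where the median went from 0.353 to 0.32). Its other 8 members lie in the MHC region and were below the expression filter. IFNB1, CXCL10, MX1 and RSAD2 were below the expression filter.

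**Figure D2:**
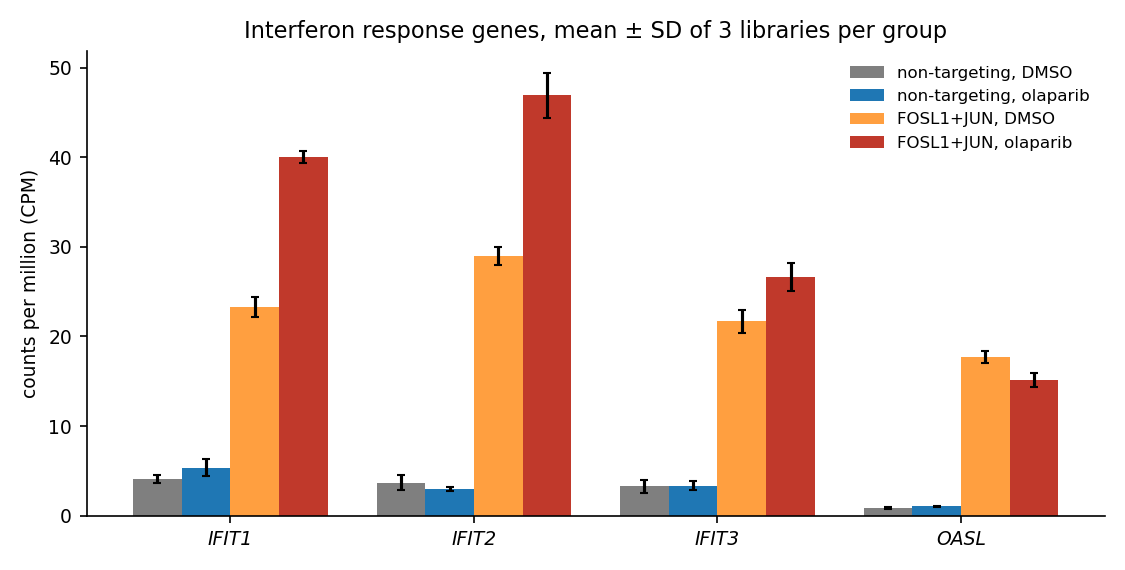
Level of 4 interferon-induced genes in CPM on the vertical axis, with bars at the mean of 3 libraries, error bars of 1 SD and 1 bar for each of the 4 groups. IFIT2 stood at 3.67 and 2.99 CPM in control cells with DMSO and olaparib, and at 29.01 and 46.9 CPM in knockdown cells.

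The stress response list was lower with knockdown in DMSO. Of 25 members 19 fell and none rose (19 and 0 adjusted over the list alone), with VLDLR, a lipoprotein receptor, at a log2 fold change of -1.13, the transcription factor DDIT3 at -0.80 and asparagine synthetase ASNS at -0.49. The camera adjusted p was 2.79e-09, or 0.00905 with an estimated correlation. Ribosomal protein genes fell in 18 of 43 cases and rose in none (18 and 0 adjusted over the list alone), with RPL9 at -0.25, RPL14 at -0.22 and RPL5 at -0.20 (camera adjusted p = 0.000789, adjusted p = 0.559 with an estimated correlation). Oxidative phosphorylation genes fell in 14 of 32 cases and rose in 1 (15 and 1 adjusted over the list alone), with UQCRC2 at -0.37, NDUFV2 at -0.29 and ATP5PO at -0.28 (camera adjusted p = 0.0032, adjusted p = 0.559 with an estimated correlation). With GC content and length offsets the ribosomal and oxidative phosphorylation lists had camera adjusted p-values of 0.181 and 0.158, and RPL5 was not called (edgeR adjusted p = 0.134). The list medians went from -0.103 to -0.0456 and from -0.126 to -0.0518, and RPL5 went from -0.20 to -0.088. Across genes, the fold change of this comparison followed GC content with a Spearman rho of 0.271, where genes are not independent replicates. Hypoxia and glycolysis gave 14 down and 3 up of 29 (14 and 3 adjusted over the list alone, camera adjusted p = 0.0138, adjusted p = 0.517 with an estimated correlation). AP-1 family genes gave 1 up and 5 down of 16 (1 and 5 adjusted over the list alone, camera adjusted p = 0.101, 0.035 with GC content and length offsets, 0.144 with offsets and an estimated correlation), including ATF3 at -0.72, FOSL2 at -0.36 and FOS at 0.78. That list holds both siRNA targets, and without them 1 of 14 rose and 3 fell, with a median of -0.08 and an unadjusted camera p of 0.25. Described AP-1 and FRA-1 targets gave 6 up and 10 down of 26 (6 and 12 adjusted over the list alone, 0.373), G2/M genes 3 and 6 of 40 (2 and 5 adjusted over the list alone, 0.158), and homologous recombination genes 1 and 3 of 30 (0 and 0 adjusted over the list alone, 0.915), where the median and mean stood above 0 and the test pointed down.

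Knockdown was compared with control in olaparib to show its effect under the drug. IFIT2 rose 15.6-fold to 46.9 ± 2.50 CPM (log2 3.96, SE 0.109, n = 3), IFIT3 7.99-fold, IFIT1 7.34-fold and OASL 14.1-fold. TGM2 and PLSCR4, a phospholipid scramblase, rose 4.37-fold and 4.13-fold. EFNB2 fell 6.25-fold (log2 -2.64, SE 0.0792), FOSL1 fell 5.92-fold (log2 -2.57, SE 0.0808) and JUN fell 3.88-fold (log2 -1.96, SE 0.0997). ADGRG1 and AMMECR1 had log2 fold changes of -1.99 and -1.80. In all 4644 genes changed (38.3%), 2308 up and 2336 down, with 349 at least 2-fold.

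Of 28 interferon genes 24 rose and 1 fell with knockdown in olaparib (24 and 1 adjusted over the list alone), with a median of 1.52 and a camera adjusted p of 8.1e-14, or 0.00441 with an estimated correlation. AP-1 family genes fell in 12 of 16 cases and rose in 2 (12 and 2 adjusted over the list alone), FOSL2 by 0.54 and ATF3 by 0.68 on the log2 scale (camera adjusted p = 0.000347, adjusted p = 0.0553 with an estimated correlation). The 12 include both siRNA targets, and without them 10 of 14 fell and 2 rose, with a median of -0.31 and an unadjusted camera p of 0.0022 (0.0116 with an estimated correlation). The rises of FOS and JDP2 and the falls of ATF2, MAFF and MAFK were not called without control olaparib library 1 (edgeR adjusted p-values from 0.0541 to 0.129) or 2 (from 0.0852 to 0.152), and each was also lost in other refits. Described AP-1 and FRA-1 targets gave 3 up and 14 down of 26 (3 and 16 adjusted over the list alone, camera adjusted p = 0.00219, adjusted p = 0.0926 with an estimated correlation). Homologous recombination genes gave 16 up and 0 down of 30 (16 and 0 adjusted over the list alone). BRCA1, a central recombination factor, stood at 35.0 ± 1.67 CPM in control cells and 48.0 ± 3.45 CPM in knockdown cells (log2 0.45, SE 0.0691), and BLM and RAD54B rose by 0.56 and 0.48. The camera adjusted p of that list was 0.0004, and the adjusted p = 0.0926 with an estimated correlation. Fanconi anaemia and checkpoint genes gave 13 up and 2 down of 28 (13 and 2 adjusted over the list alone, 0.00361, adjusted p = 0.0926 with an estimated correlation), DNA replication genes 21 and 2 of 40 (22 and 2 adjusted over the list alone, 0.0016, adjusted p = 0.284 with an estimated correlation) and G2/M genes 21 and 3 of 40 (23 and 3 adjusted over the list alone, 0.00102, adjusted p = 0.431 with an estimated correlation). PARP family and base excision repair gave 11 and 3 of 26 (11 and 4 adjusted over the list alone, 0.0341, adjusted p = 0.179 with an estimated correlation, and 0.0576 without library 1 of the knockdown olaparib group). The cGAS-STING list gave 4 and 0 of 11 (4 and 0 adjusted over the list alone, 0.0061, adjusted p = 0.0926 with an estimated correlation).

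Stress response, metabolic, ribosomal protein, mesenchymal and growth factor lists were among those lower with knockdown in olaparib. Stress response genes fell in 16 of 25 cases and rose in 3 (17 and 3 adjusted over the list alone), with PPP1R15A at -0.98, VLDLR at -0.93 and DDIT3 at -0.90 (camera adjusted p = 0.00013, adjusted p = 0.0619 with an estimated correlation). Hypoxia and glycolysis genes fell in 20 of 29 cases and rose in 4 (21 and 4 adjusted over the list alone), with hexokinase HK2 at -0.86, PFKFB3 at -0.65 and PGK1 at -0.45 (camera adjusted p = 0.00013, adjusted p = 0.163 with an estimated correlation). Ribosomal protein genes fell in 28 of 43 cases (31 adjusted over the list alone), with RPL18 at -0.28, RPS16 at -0.23 and RPS3 at -0.20 (camera adjusted p = 3.41e-05, adjusted p = 0.393 with an estimated correlation). Mesenchymal genes gave 3 up and 13 down of 23 (3 and 14 adjusted over the list alone, 0.00098, adjusted p = 0.187 with an estimated correlation), and growth factor ligands and receptors 2 and 11 of 21 (2 and 12 adjusted over the list alone, 0.00154, adjusted p = 0.0964 with an estimated correlation). Cholesterol synthesis gave 2 and 13 of 28 (2 and 15 adjusted over the list alone, 0.00219, adjusted p = 0.187 with an estimated correlation) and lysosome and autophagy 2 and 10 of 27 (2 and 10 adjusted over the list alone, 0.00833, adjusted p = 0.284 with an estimated correlation). Oxidative phosphorylation gave 2 up and 10 down of 32 (2 and 10 adjusted over the list alone, camera adjusted p = 0.0187, adjusted p = 0.441 with an estimated correlation), and 0.148 with GC content and length offsets, where the median went from -0.0939 to -0.0554. MAPK feedback genes gave 3 and 10 of 22 (3 and 11 adjusted over the list alone, camera adjusted p = 0.0375, adjusted p = 0.195 with an estimated correlation). The MAPK call was lost with GC content and length offsets (0.0537), without library 3 of the knockdown olaparib group (0.0533) and without both libraries with the strongest GC trend (0.0617), while the median of -0.128 went to -0.114, -0.124 and -0.123.

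**Figure D3:**
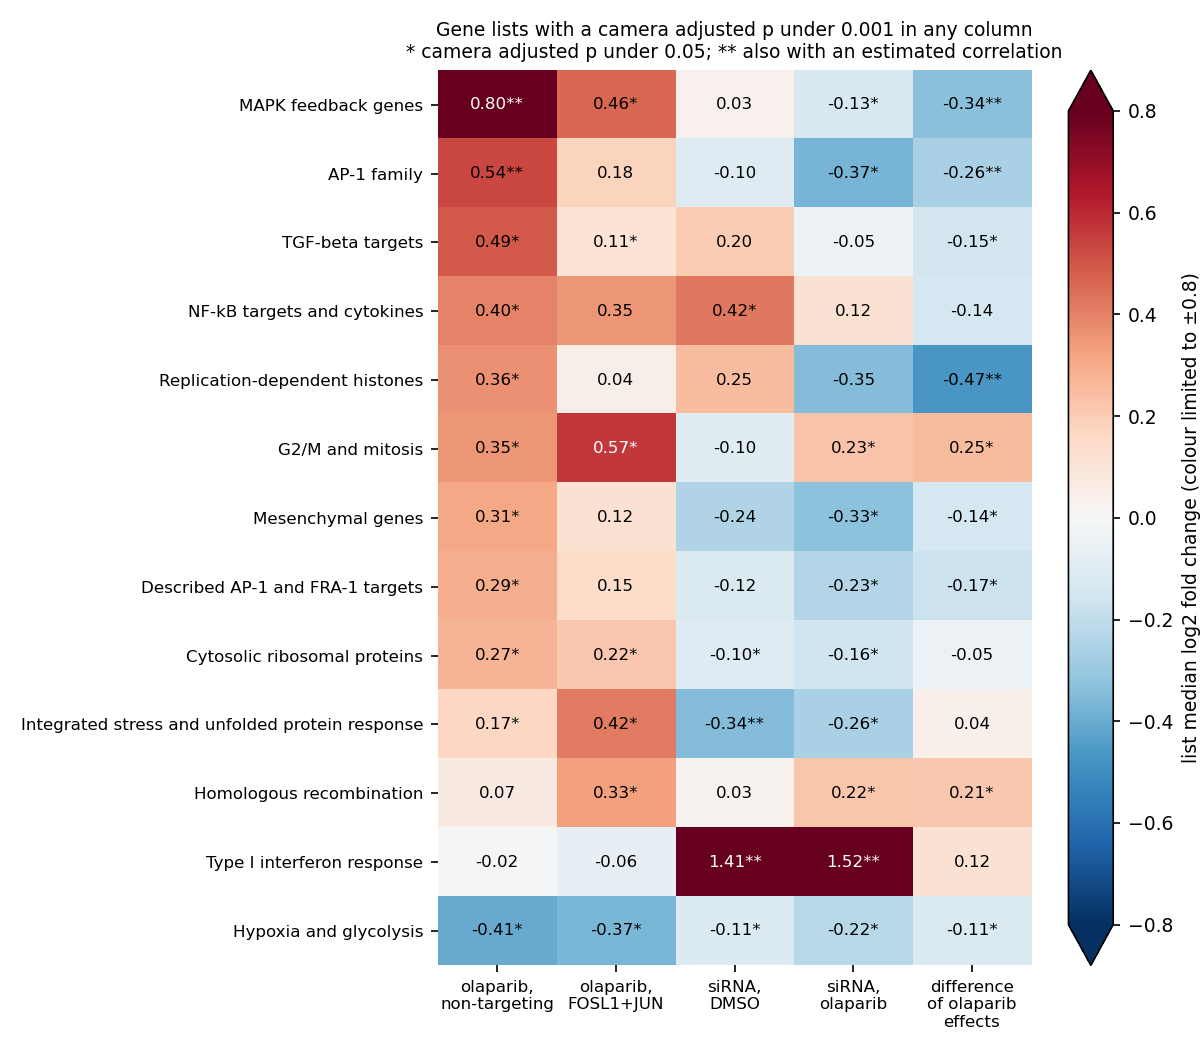
Median log2 fold change of 13 gene lists (vertical axis) in 5 comparisons (horizontal axis), as colour limited to 0.8 in either direction, for lists with a camera adjusted p below 0.001 in at least 1 of them. A star marks a camera adjusted p below 0.05 and 2 stars a call that also held with an estimated correlation, as for the interferon list in both knockdown comparisons (medians 1.41 and 1.52).

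The interaction asked whether olaparib acted differently in knockdown and control cells. The treatments differed in the remaining share of the targeted genes. In DMSO it was 37.4% for FOSL1 and 38.2% for JUN, and in olaparib 16.8% and 25.8%. TXNIP rose with olaparib by 2.52 on the log2 scale in control cells and by 0.79 in knockdown cells, a difference of -1.73 (SE 0.118, edgeR adjusted p = 1.13e-07). CTGF rose by 3.04 and 1.98, a difference of -1.06 (SE 0.0867, edgeR adjusted p = 1.6e-06). The stress sensor GADD45A rose by 1.30 in control cells and had a value of 0.27 in knockdown cells, and CITED4 rose by 2.15 against a value of 0.54. BRCA1 fell by 0.28 in control cells and rose by 0.32 in knockdown cells, a difference of 0.59 (SE 0.0979, edgeR adjusted p = 0.00188). ATAD5, which unloads the replication clamp, likewise went from -0.62 to 0.36, and the difference for IFIT2 was 1.00 (SE 0.174, edgeR adjusted p = 0.0028). A difference was called for 690 genes (5.69%), 344 higher and 346 lower in knockdown cells, of which 26 were at least 2-fold, 3 of these higher and 23 lower. Leaving out 1 library moved the count to between 308 (without control olaparib library 1) and 1130 (without knockdown olaparib library 1). It was 434 and 349 without control DMSO libraries 1 and 2, 321 without control olaparib library 2, 423 without knockdown DMSO library 2 and 343 without knockdown olaparib library 2.

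The MAPK feedback and AP-1 family lists were lower in the interaction by camera, with most members not called on their own. Of 22 MAPK feedback genes 8 had a called difference, all of these lower (12 adjusted over the list alone), with a median difference of -0.34. They included the phosphatase DUSP1 (1.37 in control cells, 0.37 in knockdown cells), DUSP6 (1.27 and 0.70) and MYC (1.55 and 1.16). The camera adjusted p was 1.99e-07, or 0.0349 with an estimated correlation. Of 16 AP-1 family genes 3 were lower and none higher (6 and 0 adjusted over the list alone), which were FOSL1 with a difference of -1.14, JUN of -0.57 and ATF7 of -0.43 (camera adjusted p = 0.000474, or 0.0475 with an estimated correlation). The difference of JUN was not called with GC content and length offsets (edgeR adjusted p = 0.0561), nor without control DMSO library 1 (0.0626) or 3 (0.0584), control olaparib library 1 (0.0535), 2 (0.074) or 3 (0.0512), knockdown DMSO library 2 (0.07) or knockdown olaparib library 2 (0.0793), nor without both libraries with the strongest GC trend (0.069). Its size was -0.49 with the offsets and -0.50 without both of those libraries. Of 9 histone genes 2 were lower (3 adjusted over the list alone), HIST2H2BE at -1.24 and HIST1H2BK at -0.58, with a camera adjusted p of 0.000909, or 0.0475 with an estimated correlation. Both are members of a family with shared sequence. Of 16 listed histone genes only 9 passed the expression filter, so the call does not speak for the rest, such as HIST1H4C. Described AP-1 and FRA-1 targets gave 5 lower of 26 (7 adjusted over the list alone), including the kinase SPHK1 at -1.21 and the protease PLAU at -0.35 (camera adjusted p = 0.00184, adjusted p = 0.089 with an estimated correlation).

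The G2/M and homologous recombination lists were higher in the interaction by camera, and neither call was kept with an estimated correlation. Of 40 G2/M genes 16 had a higher difference and none a lower one (23 and 1 adjusted over the list alone), with BUB1B, a spindle checkpoint kinase, at 0.44, KIF23 at 0.37 and PRC1 at 0.36 (camera adjusted p = 9.26e-09, adjusted p = 0.271 with an estimated correlation). Of 30 homologous recombination genes 5 were higher and none lower (9 and 0 adjusted over the list alone), with the nuclease subunit EME1 at 0.68, BRCA1 at 0.59 and RAD54B at 0.54 (camera adjusted p = 5.31e-06, adjusted p = 0.0504 with an estimated correlation). Fanconi anaemia and checkpoint genes gave 6 higher of 28 (7 adjusted over the list alone, 0.00583, adjusted p = 0.105 with an estimated correlation), and DNA replication genes 6 of 40 (8 higher and 1 lower adjusted over the list alone, 0.00583, adjusted p = 0.396 with an estimated correlation). Across genes the difference followed GC content with a Spearman rho of -0.48, where genes are not independent replicates. Median GC content was 43.8% for the G2/M list and 42.1% for homologous recombination, against 56.6% for the AP-1 family and 50.7% for MAPK feedback genes. Library 2 of the knockdown DMSO group and library 3 of the knockdown olaparib group had the strongest GC trends of the 12 libraries (rho 0.376 and -0.516). Without both of them 433 genes had a called difference, and with offsets for GC content and length 1062 did, 563 of them shared with the 690 in the same direction.

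**Figure D4:**
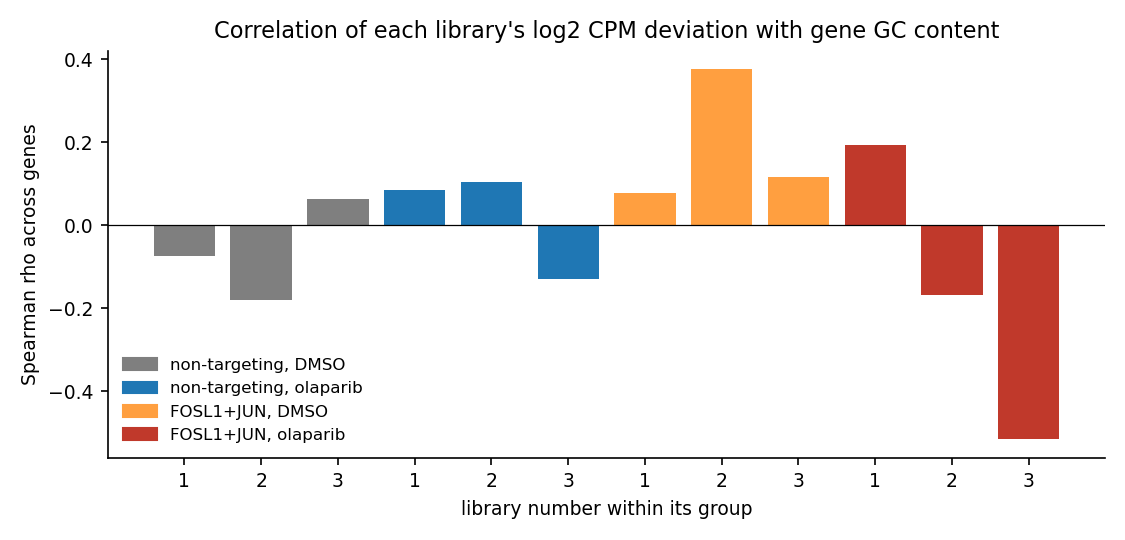
Spearman rho between gene GC content and a library's log2 CPM deviation from the gene's mean (vertical axis), with 1 bar for each of the 12 libraries. Values ran from -0.516 to 0.376, both in the knockdown groups.

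Other lists were lower in the interaction, each lost with an estimated correlation. TGF-beta targets gave 3 lower of 19 (6 adjusted over the list alone, camera adjusted p = 0.00333, adjusted p = 0.229 with an estimated correlation), YAP/TEAD targets 4 lower and 2 higher of 21 (8 and 3 adjusted over the list alone, 0.0111, adjusted p = 0.271 with an estimated correlation) and growth factor ligands and receptors 3 lower of 21 (4 adjusted over the list alone, 0.0155, adjusted p = 0.246 with an estimated correlation). Mesenchymal genes gave 3 lower and 1 higher of 23 (6 and 1 adjusted over the list alone, 0.0111, adjusted p = 0.393 with an estimated correlation), a call lost without library 1 of the control DMSO group (0.107). Hypoxia and glycolysis gave 4 lower of 29 (10 lower and 2 higher adjusted over the list alone, 0.0292) and cholesterol synthesis 2 lower of 28 (2 adjusted over the list alone, 0.0302), each with an adjusted p = 0.396 with an estimated correlation. The hypoxia call was lost without control DMSO library 2 (0.0648), control olaparib library 1 (0.0549), knockdown DMSO library 1 (0.0778) or knockdown olaparib library 1 (0.0503). The cholesterol call was lost without control DMSO library 2 (0.0842), knockdown DMSO library 3 (0.0758) or knockdown olaparib library 3 (0.0505). For interferon genes the interaction did not pass (3 higher and 0 lower of 28, 3 and 0 adjusted over the list alone, camera adjusted p = 0.445), nor did it for ribosomal protein genes (0 of 43, 0.219) or the stress response (4 higher and 1 lower of 25, 7 and 2 adjusted over the list alone, 0.219, and 0.0314 with GC content and length offsets, 0.26 with offsets and an estimated correlation).

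**Figure D5:**
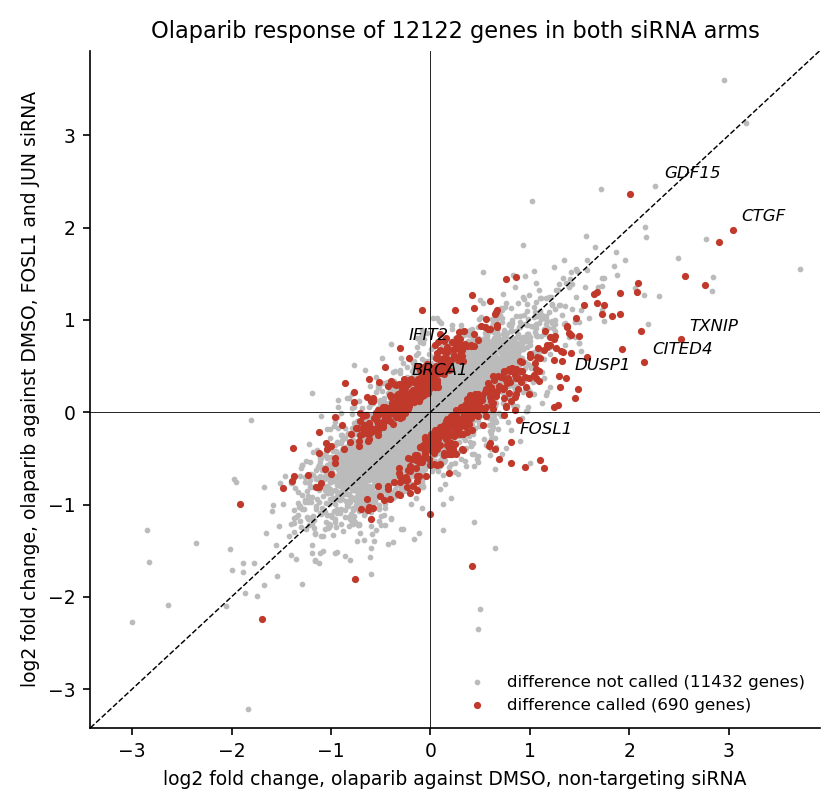
Log2 fold change with olaparib in control cells (horizontal axis) against that in knockdown cells (vertical axis) for 12122 genes, with the 690 genes whose difference was called in red and a dashed line where both are equal. Pearson's r across genes was 0.779, and genes are not independent replicates.

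The calls for olaparib overlapped between the arms, which share no library. In both, 1973 genes rose against 689.9 expected for independent lists, 1839 fell against 673.4 expected, and 53 were called in opposite directions against 1363 expected. The covariance of the fold changes was 0.129, where simulated unchanged groups gave 8.15e-05. Of the 53 genes with opposite calls, 25 rose in control cells and fell in knockdown cells and 28 did the reverse. The difference was called for all 53, which their selection by opposite calls in the same model makes likely in advance. Both knockdown comparisons likewise shared 1055 rises (338.9 expected) and 1208 falls (355.4 expected), with 55 opposite calls (694.1 expected). The effects of olaparib and of knockdown against the same control DMSO libraries were also set against each other, with 1291 opposite calls (848.6 expected), 347 shared rises (420.8 expected) and 319 shared falls (427.5 expected). Their fold changes had a Pearson r of -0.151 and a Spearman rho of -0.138 across genes, while 20 simulations of unchanged groups against those controls gave a mean r of 0.516. The covariance was -0.0233 against a simulated 0.0103, a difference of -0.0336. The 3 shared controls cannot be split into parts of at least 2 libraries each, and without control DMSO library 3 the r was -0.0617.

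Knockdown with olaparib was last set against control cells with DMSO, the combined change. IFIT2 rose 12.6-fold (log2 3.66, SE 0.107, n = 3), IFIT1 9.80-fold, IFIT3 8.17-fold and OASL 16.8-fold, and ID4 and TIMP3, an inhibitor of metalloproteinases, each rose 5.82-fold. AMMECR1 (log2 -2.12), NDRG1 (log2 -2.11), DEPP1 (log2 -2.10), SLC6A6 (log2 -2.08) and COL13A1 (log2 -2.04) had the largest falls under the naming rule. FOSL1 fell by 1.75 and JUN fell by 1.96 on the log2 scale. In all 5721 genes changed (47.2%), 2882 up and 2839 down, with 435 at least 2-fold.

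Interferon genes gave 22 up and 1 down of 28 in the combined change (22 and 1 adjusted over the list alone, camera adjusted p = 9.66e-11, or 0.0114 with an estimated correlation). G2/M genes gave 36 and 0 of 40 (37 and 0 adjusted over the list alone), with TOP2A at 0.98, KIF2C at 0.77 and NUSAP1 at 0.73 (camera adjusted p = 4.65e-14, adjusted p = 0.127 with an estimated correlation). Hypoxia and glycolysis genes fell in 25 of 29 cases and rose in 2 (25 and 2 adjusted over the list alone), with BNIP3 at -1.18, PGK1 at -1.04 and ALDOC at -1.02 (2.91e-10, adjusted p = 0.0672 with an estimated correlation). NF-kB targets and cytokines gave 12 and 1 of 17 (12 and 1 adjusted over the list alone), with CCL2 up 3.51-fold, ICAM1 2.02-fold and CSF1 1.79-fold (1.68e-05, adjusted p = 0.0859 with an estimated correlation). MAPK feedback genes gave 13 and 2 of 22 (13 and 2 adjusted over the list alone), with SPRY4 up 2.75-fold, SPRY2 2.60-fold and DUSP4 2.29-fold (8.06e-05, adjusted p = 0.0672 with an estimated correlation). Homologous recombination gave 20 and 2 of 30 (22 and 4 adjusted over the list alone), with RAD54B at 0.75, RBBP8 at 0.74 and BLM at 0.73 (0.000217, adjusted p = 0.092 with an estimated correlation), and Fanconi anaemia and checkpoint 16 and 3 of 28 (17 and 3 adjusted over the list alone, 0.0014, adjusted p = 0.0859 with an estimated correlation). Ribosomal protein genes gave 23 and 0 of 43 (23 and 0 adjusted over the list alone, 0.00045, adjusted p = 0.603 with an estimated correlation), TGF-beta targets 12 and 2 of 19 (13 and 2 adjusted over the list alone, 0.000885, adjusted p = 0.127 with an estimated correlation) and YAP/TEAD targets 12 and 3 of 21 (12 and 3 adjusted over the list alone, 0.00292, adjusted p = 0.171 with an estimated correlation). Cholesterol synthesis gave 2 up and 14 down of 28 (2 and 14 adjusted over the list alone, 0.0014, adjusted p = 0.171 with an estimated correlation). Epithelial genes (6 and 2 of 9, 6 and 2 adjusted over the list alone, 0.0368, adjusted p = 0.364 with an estimated correlation) lost their call without any 1 of knockdown olaparib libraries 1, 2 and 3 (0.113, 0.0879 and 0.0635). The p53 targets (12 and 3 of 26, 12 and 3 adjusted over the list alone, 0.0374, adjusted p = 0.125 with an estimated correlation) lost theirs without control DMSO library 2 (0.0518). AP-1 family genes did not pass (6 and 4 of 16, 7 and 5 adjusted over the list alone, 0.66), with a median of 0.21 and a mean of -0.05. Without the siRNA targets 6 of 14 rose and 2 fell, with an unadjusted camera p of 0.0687. The fall of ATF3 was not called without control DMSO library 1 (edgeR adjusted p = 0.13) or knockdown olaparib library 1 (0.131), and it was also lost in other refits. The rise of JUNB was not called without control DMSO library 2 or 3 (0.0517 in each).

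Over all 6 comparisons, 9 of 79 list calls held with an estimated correlation. These were MAPK feedback and AP-1 family genes for olaparib in control cells, interferon and stress response genes for knockdown in DMSO, interferon genes for knockdown in olaparib and for the combined change, and MAPK feedback, AP-1 family and histone genes in the interaction. With GC content and length offsets as well, the MAPK, AP-1 and histone calls were not kept (adjusted p = 0.0983 and 0.0657 for olaparib in control cells and 0.0642 for all 3 lists in the interaction, with an estimated correlation). Their medians with offsets were 0.82 and 0.53 for olaparib in control cells, from 0.80 and 0.54, and -0.27, -0.20 and -0.45 in the interaction, from -0.34, -0.26 and -0.47. The authors' deposited table, over 12106 genes, called 5791 genes for olaparib in control cells, 5933 in knockdown cells, 3768 and 4788 for knockdown in DMSO and in olaparib, 879 for the interaction and 5845 for the combined change. Of the calls made here 5613, 5766, 3584, 4597, 690 and 5670 were also made in the authors' deposited table with the same direction, and 0 with the opposite one.

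Markers of other cell types were also measured. Of 21 haematopoietic markers 2 were tested, and PTPRC, the pan-leukocyte marker, reached at most 0.475 CPM in any library. CD68, a lysosomal protein that cell lines also express, stood at 38.6 and 51.8 CPM in control cells with DMSO and olaparib and at 19.4 and 22.3 CPM in knockdown cells. Of 12 endothelial markers 3 were tested, with TEK at 0.698 and 0.338 CPM in control cells and 4.83 and 2.52 CPM in knockdown cells, EGFL7 at 39.6 to 53.2 CPM and ROBO4 at 1.69 to 4.48 CPM over the group means. Of 16 luminal breast markers 9 were tested, of which 5 rose and 3 fell with knockdown in DMSO (camera adjusted p = 0.373). PRLR stood at 93.0 CPM in control cells and 164 CPM in knockdown cells with DMSO, ERBB2 at 102 and 134 CPM and CA12 at 102 and 55.6 CPM, while ESR1, PGR and TFF1 reached at most 0.0698, 0 and 0 CPM in any library. These luminal genes were chosen after their values were seen. The 13 mitochondrially encoded genes are not in the table used and were not analysed here.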

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

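Every result here was singled out because the olaparib effect differed between control and knockdown cells in a test of the difference itself, and the splits of the libraries and the tests on GC content, depth and the targeted genes were chosen after the result was seen.

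The difference was called for 690 genes, and for between 308 (without control olaparib library 1) and 1130 (without knockdown olaparib library 1) with 1 library left out. Of 100 regroupings of the libraries within both arms, the real one included, 1 gave as many (the real one), and the highest other count was 196. For the 14 lists with a called difference, 1 of the 100 regroupings gave as many (the real one), and the highest other count was 12. These regroupings exchange DMSO and olaparib libraries, so the drug effect itself enters their spread, and they do not test the difference alone. Whether chance accounts for the counts was therefore left open.

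Lists lower in the test of the difference had median differences on the log2 scale of -0.336 for MAPK feedback genes, -0.261 for the AP-1 family, -0.468 for replication-dependent histones, -0.169 for described AP-1 and FRA-1 targets, -0.146 for TGF-beta targets, -0.164 for YAP/TEAD targets, -0.167 for growth factor ligands and receptors, -0.139 for mesenchymal genes, -0.114 for hypoxia and glycolysis and -0.0717 for cholesterol synthesis. Hypoxia and glycolysis genes fell with olaparib in both arms, with means of -0.326 in control cells and -0.403 in knockdown cells. Cholesterol genes had means of -0.0539 and -0.156. By the mean, a difference below 0 was thus a larger fall for both lists, while the hypoxia median went from -0.406 to -0.367. Lists higher in that test had medians of 0.252 for G2/M and mitosis, 0.213 for homologous recombination, 0.144 for Fanconi anaemia and checkpoint and 0.131 for DNA replication. Of the 14 list calls, 3 held with an estimated correlation, those of MAPK feedback, AP-1 family and histone genes, and the higher lists had adjusted p = 0.271, 0.0504, 0.105 and 0.396 with an estimated correlation. With GC content and length offsets the median was -0.0968 for YAP/TEAD targets and likewise for growth factor ligands and receptors, and -0.112 for described AP-1 and FRA-1 targets.

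Among single genes, differences below 0 were -1.73 for TXNIP, -1.61 for CITED4, -1.24 for HIST2H2BE, -1.21 for SPHK1, -1.14 for FOSL1, -1.06 for CTGF, -1.03 for GADD45A and -0.999 for DUSP1. EFNB2 had a difference of -0.69, as its rise with olaparib was 2.09 in control cells and 1.40 in knockdown cells. ADGRG1 had -0.63, INHBA -0.58, HIST1H2BK -0.58, JUN -0.57, DUSP6 -0.57, DEPP1 -0.55, SPRY4 -0.45, PFKFB3 -0.43, ATF7 -0.43, MYC -0.39, DUSP4 -0.36, PLAU -0.35 and ALDOC -0.30. DEPP1 and ALDOC fell with olaparib in both arms, and further in knockdown cells (-2.24 against -1.70 and -0.94 against -0.63). Differences above 0 were 0.31 for NUSAP1, 0.36 for ACTA2, 0.36 for PRC1, 0.37 for KIF23, 0.43 for TOP2A, 0.44 for BUB1B, 0.45 for ASNS, 0.53 for BLM, 0.54 for RAD54B, 0.59 for BRCA1, 0.65 for FAM46A, 0.67 for RAB7B and 0.68 for EME1. FAM46A and RAB7B fell with olaparib in both arms, and less in knockdown cells (-0.74 against -1.39 and -0.82 against -1.49). FAM72B, whose reads cannot be assigned with certainty among near-identical copies, had 0.85. CENPE had 0.88 (-0.77 in control cells, 0.11 in knockdown cells), CCDC18 0.90, ATAD5 0.98 and IFIT2 1.00. The call for CENPE was lost without control DMSO library 1 (edgeR adjusted p = 0.0631), control olaparib library 1 (0.076) or 2 (0.0712), knockdown DMSO library 2 (0.0881) or 3 (0.0537) or knockdown olaparib library 2 (0.052). The call for CCDC18 was lost without control olaparib library 1 (0.0586) or 2 (0.0553), and both calls without the 2 libraries with the strongest GC trend (0.12 for CENPE, 0.103 for CCDC18). Without those 2 libraries the differences were 0.72 for CENPE and 0.85 for CCDC18. The call for JUN was lost in 7 of the 12 refits without 1 library and with offsets, with the values given beside its difference in the interaction.

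The higher olaparib effect on G2/M and homologous recombination genes in knockdown cells went with a GC trend across libraries, and the median GC content of these lists was 43.8% and 42.1%. With offsets for GC content and length, both lists stayed higher in all 12 refits that each left out 1 library, with a highest camera adjusted p of 0.00209, and the medians went from 0.252 to 0.208 and from 0.213 to 0.185. With counts thinned to the smallest total, the higher camera adjusted p of the pair was 9.69e-06. These tests argue against GC content, length and unequal depth as the whole cause, while the correlation between members stays a limit (adjusted p = 0.271 and 0.0504 with an estimated correlation, 0.26 and 0.0642 with offsets as well). A candidate explanation is that more knockdown cells were in G2 or mitosis under olaparib, and cell cycle phase was not measured.

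The lower olaparib effect on MAPK feedback and AP-1 family genes in knockdown cells kept its call with GC content and length offsets in all 12 refits (highest camera adjusted p = 0.0121, medians from -0.34 to -0.27 and from -0.26 to -0.20) and with thinned counts (higher camera adjusted p of the pair, 0.00202), though not with offsets and an estimated correlation together (adjusted p = 0.0642 for both with an estimated correlation). Without FOSL1 and JUN, the 14 other AP-1 family genes had a median difference of -0.22 and a camera p of 0.00177, with 1 gene lower and none higher, so the targeted genes did not carry the list alone. These values argue against GC content and length, against depth and against the targets themselves, each tested separately, as the whole cause. The AP-1 family list without the targets was not tested with the offsets. It may be that part of the drug-induced rise of MAPK feedback and AP-1 family genes needs FRA-1 or JUN, a hypothesis from these data that none of these tests decides. An effect of the siRNA mixture on other genes stays open, as the design has 1 mixture.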

How the results depend on the processing

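Tests chosen after the result was seen were the GC content and length offsets, the thinned counts and the model without both libraries with the strongest GC trend, and the other alternatives were planned. Over 242 gene results and 4800 alternative values, 4689 kept the call or its absence, 87 lost and 24 gained a call. None (0) changed direction while called in either model. A change of sign in a gene called in neither model was counted as kept. Over 79 called lists and 1501 values, 1406 kept the call and 95 lost it, 70 of these with an estimated correlation, and 0 reversed. Requiring a 2-fold change as well lowered the counts of changed genes by construction to 372, 293, 288, 349, 26 and 435 for olaparib in control cells, olaparib in knockdown cells, knockdown in DMSO, knockdown in olaparib, the interaction and the combined change. An adjusted p below 0.01 left 2349 genes for knockdown in DMSO and 197 for the interaction, again by construction. For the interaction, 341 genes were higher and 351 lower with DESeq2 size factors, 378 and 412 with the DESeq2 Wald test, and 350 and 359 with limma-voom. They numbered 343 and 349 with the default filter of edgeR, and 405 and 443 without an expression filter. With only the 2 groups compared, 1726 rose and 1604 fell for knockdown in DMSO, and 2365 and 2373 for knockdown in olaparib. The interaction count of 690 became 1062 with GC content and length offsets, where the common dispersion went from 0.00372 to 0.00168, and 433 without both libraries with the strongest GC trend. Leaving out 1 library gave between 308 genes (without control olaparib library 1) and 1130 (without knockdown olaparib library 1). Other libraries that moved it by over 1.5 times were control DMSO libraries 1 (434) and 2 (349), control olaparib library 2 (321), knockdown DMSO library 2 (423) and knockdown olaparib library 2 (343). The cause was not tested. With an estimated correlation 2, 0, 2, 1, 3 and 1 lists passed in the 6 comparisons in the same order. With fry, which does not compare a list with other genes, 25, 23, 24, 27, 17 and 29 passed in that order. For olaparib in knockdown cells 10 lists passed, 16 with offsets, and between 7 (without knockdown olaparib library 1) and 16 (without knockdown DMSO library 2) with 1 library left out, and the cause was not tested. The correlation of the olaparib and knockdown effects ran from -0.159 (without knockdown DMSO library 2) to -0.0617 (without control DMSO library 3). With counts thinned to the smallest total, 568 genes were called for the interaction. At the real depths with 3 libraries per group, 12% of genes changed by the smallest simulated fold were called for it, and the simulation did not vary depth.

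Replicate numbers were shared between groups, but the labels do not say that they pair libraries. Of 18 same-numbered pairs, 2 had deviations correlated above 0.1 (range -0.269 to 0.196), and 3 of 12 libraries correlated best with their own number, so the numbers were not taken as pairs. With the number as a block, 5570, 5696, 3507, 4526, 613 and 5629 genes were called in the 6 comparisons. No list call was lost under the block, and 5 of 242 gene calls were, with edgeR adjusted p-values of 0.0592 for JUN and 0.0786 for CENPE in the interaction and of 0.0623 for MAFF, 0.0516 for MAFK and 0.0558 for JDP2 for knockdown in olaparib.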

Other observations

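The tests with GC content and length offsets, of haematopoietic markers, of the MHC region and with other splits of the libraries were chosen after the result was seen.

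Of the 53 genes with opposite calls for olaparib in the arms, 8 are described here, all chosen after their values were seen, and no group of genes was tested among the 53. FANCI fell by 0.15 on the log2 scale with olaparib in control cells and rose by 0.24 in knockdown cells (difference 0.39, edgeR adjusted p = 0.00837). The helicase WRN fell by 0.25 and rose by 0.27 (difference 0.52, edgeR adjusted p = 0.00406), and HLTF, a fork remodeller, fell by 0.29 and rose by 0.27 (difference 0.56, edgeR adjusted p = 0.000956). SLC7A11, the cystine transporter, fell by 0.21 and rose by 0.59 (difference 0.80, edgeR adjusted p = 0.000956), and CHAC1, which degrades glutathione, fell by 0.40 and rose by 0.34 (difference 0.74, edgeR adjusted p = 0.005). In the other direction, the vasodilator peptide gene ADM rose by 0.59 and fell by 0.37 (difference -0.96, edgeR adjusted p = 0.00047), and VASP, an actin regulator, rose by 0.35 and fell by 0.15 (difference -0.50, edgeR adjusted p = 0.0012). The chaperone HSPA8 rose by 0.20 and fell by 0.15 (difference -0.36, edgeR adjusted p = 0.00352).

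Many genes of the MHC region were listed at or near 0 counts. By the RefSeq annotation of GRCh38.p14, 160 protein-coding genes of the table lie in that region, of which 13 (8.13%) passed the expression filter and 107 had 0 counts in all 12 libraries. Elsewhere 11397 of 18822 (60.6%) passed. RPS18, a ribosomal protein gene of the region that every cell uses, had 5 counts over all libraries, and ABCF1, FLOT1 and DDX39B had 0. Low counts of such genes were not confined to the region, as RPS9, a ribosomal protein gene outside it, had 21. A low count in this region was therefore not read as absence of expression. HLA-B and HLA-C, among the 8 tested antigen presentation members, and HSPA1A of the heat shock list lie in the region too, and entered the list tests with the counts as deposited.

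The rise of interferon genes with knockdown, in DMSO and in olaparib, was weighed against technical explanations. With GC content and length offsets the list median in DMSO was 1.45 and stayed between 1.41 and 1.47 in 12 refits that each left out 1 library, which argues against GC content and length. The 19 haematopoietic markers below the expression filter summed to 1.33 ± 0.291 CPM in control cells and 0.808 ± 0.306 CPM in knockdown cells with DMSO (SD, n = 3), and all 21 to 41.3 ± 1.90 and 21.5 ± 2.21 CPM, while the 28 interferon genes went from 320 ± 10.2 to 548 ± 13.8 CPM, which argues against RNA from blood cells. A response to the siRNA mixture itself, such as sensing of double-stranded RNA, cannot be told apart from the reduction of FOSL1 and JUN, because the design holds 1 mixture against these genes. Release of interferon genes from repression by AP-1 is another candidate explanation, and it was not tested.

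The ribosomal protein list was lower with knockdown in DMSO with a median of -0.10 (between -0.13 and -0.08 in 12 refits without 1 library), and with GC content and length offsets the median was -0.05 (between -0.05 and -0.03 in 12 refits) and the camera adjusted p 0.181, so the call ended because the fold change itself shrank with the trend removed. With knockdown in olaparib the median went from -0.16 to -0.09 (between -0.10 and -0.07 in 12 refits) and the camera adjusted p was 0.00494, a call that was not kept with an estimated correlation (adjusted p = 0.393 with an estimated correlation, 0.388 with offsets as well).

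For the comparisons of 3 libraries against 3, only 10 splits exist and a share under 0.05 cannot be reached. Every other split mixes libraries of both real groups, so the real effect enters its spread and part of that effect stays in its contrast. The counts of the other splits are therefore not a chance level, and no conclusion was drawn from them. Counts of changed genes were 5676, 3624, 4644 and 5721 for olaparib in control cells, knockdown in DMSO, knockdown in olaparib and the combined change, with a highest other count of 0 in each, and 5823 for olaparib in knockdown cells, with a highest other count of 78. In each, 1 split, the real one, gave as many genes. Counts of called lists were 16, 10 and 18 for olaparib in control cells, olaparib in knockdown cells and knockdown in olaparib, with highest other counts of 14, 8 and 14. For knockdown in DMSO 8 lists were called, 5 of the 10 splits gave as many and the highest other count was 10. For the combined change 13 were called, 2 of the 10 splits gave as many and the highest other count was 13.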
